A study of Caenorhabditis elegans with 3 samples.

How the data were processed

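RNA of the nematode Caenorhabditis elegans was measured on 3 two-colour DNA microarrays. On each array, total RNA of glp-4 animals at the L3 larval stage was hybridised together with a wild-type mixed reference RNA. The 3 arrays carried preps 1, 3 and 4, which were taken as replicates 1, 3 and 4 of a single group; the labels do not say how the preps were grown or whether they came from separate cultures, so p-values here measure only the spread between these 3 samples, which may be technical. Letters in the array titles, read here as an array series, place preps 3 and 4 together and prep 1 apart. The titles also hold what reads as a date, which splits the preps in the same way.

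The authors deposited a value table of 21632 probes and 3 arrays, used here in place of scanner files, which were not used. Its values are log2 ratios of the channels of each array, as read from the deposited numbers: below a ratio of 1, 100% of the values on each array equalled the log2 of a ratio kept to 3 decimals, within a tolerance of 0.01 thousandths. The array medians of the deposited log2 values were -0.0072 for prep 1, -0.0247 for prep 3 and -0.0262 for prep 4, so no further centring had been applied after the logarithm. The scanner, background correction and normalization are not given in the sources used here, and no intensities were used, so it is unknown which probes lay near background. The lowest ratio was 8 thousandths, on the prep 4 array, where the rounding is coarse.

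The labels give the reference as channel 1 and glp-4 as channel 2 and name no dye, so the direction of the ratio is not stated. Positive values were read as higher in glp-4 L3, which is the likely direction, for 2 reasons. Two-colour ratios are commonly stored as channel 2 over channel 1, and glp-4 mutants are known for an underproliferated germ line, so genes of germ cells should lie below a wild-type mixed reference. Their values lay there (report), so the side on which germline genes lie was partly set by this reading. Genotype and stage differ together in this comparison, so low values of these genes cannot be assigned to genotype alone. If the ratio ran the other way, each direction below would turn, and the counts and sizes would stand.

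Gene names came from a platform annotation that pairs probes with genes. It gave 1 gene for 16450 probes, several genes for 247 and none for 4935. Of the single-gene probes, 16360 matched a gene of the RefSeq annotation of assembly WBcel235 by gene number and 5 more by transcript accession; the other 85 kept the annotation's name. No build is named for the probes, so no coordinates are printed. The only probe of glp-4 itself was shared with another gene, so glp-4 has no value here.

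Each array was centred on its median, and probes of a gene were averaged per array. Probes with no gene or several genes stayed as features of their own. Features measured on all 3 arrays entered the test, 19580 in all, of which 14686 were named genes. The mean log2 ratio was tested against 0 with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The reference counts as a single control RNA, so the test leaves out the spread of the control. Because each array was centred, a change is relative to the median probe. Of 1374 genes with several probes, 1 had probes past the threshold in opposite directions.

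20 gene lists were fixed before the data were examined. They were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, adjusted over the 20 lists). Alternatives for the lists were camera with an estimated correlation, which rests on 2 residual degrees of freedom, camera on ranks, and fry, which asks whether the genes of a list move, on balance, one way from no change, and so is not a test against the other genes. Other alternatives were values as deposited, arrays scaled to the same median absolute deviation, quantile normalization, features measured on at least 2 arrays, each probe alone, a robust variance prior, a 2-fold limit, and each prep left out in turn. Array weights were added after seeing the data. The array series as a random block could not be fitted, because limma's duplicateCorrelation returned no value for 3 arrays; preps 3 and 4 alone give the value within a series.

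Named genes followed a rule fixed beforehand: the 12 largest mean changes in each direction among named genes past the threshold with the same sign on all arrays, and for each list up to 4 members past the threshold in its main direction and up to 2 in the other. Of genes outside the rule, vit-6 in the report and members of gene classes in the closing section were chosen after their values were seen.

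The procedure was tested on simulated data with 19580 features, 200 of them changed, in 20 runs. With 3 arrays it found 2% of changes of 1 log2 unit, 76.9% of 2 units and 92.6% of 3 units, and 5.7% of its calls were false. With 2 arrays the shares were 0.1%, 5.8% and 49.4%, with 7.8% of calls false. A list of 37 genes shifted by 1 unit was found in 20 of 20 runs. The simulated errors were independent between genes, and the 200 changed features were a smaller share than the 16.6% called in the data. The shares found and the list result therefore hold for that setting and not for these data. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of each value.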

Results

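The series compared glp-4 animals at the L3 larval stage with a wild-type mixed reference on 3 two-colour arrays, 1 for each of preps 1, 3 and 4. The gene glp-4 encodes a valyl-tRNA synthetase, and its temperature-sensitive mutants are used as animals with few germ cells. The comparison therefore sets larvae of this genotype against a pool of wild-type RNA, and genotype and stage differ together. Values were obtained for 21462 probes with prep 1, 21379 with prep 3 and 21239 with prep 4. The SD of the log2 ratios over probes was 0.71 for prep 1, 0.963 for prep 3 and 1.139 for prep 4. All values are log2 ratios read as glp-4 L3 over reference, the likely direction, and are given as mean ± SD of the 3 arrays (n = 3).

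Of the 12 named genes farthest below the reference, 4 belonged to the oocyte and maternal list fixed beforehand. In all, 1617 features were higher and 1638 were lower in glp-4 L3 (limma, Benjamini-Hochberg adjusted p under 0.05), which is 16.6% of the 19580 tested. Of these, 1413 higher and 1280 lower features were named genes, and 1185 in each direction differed at least 2-fold. The sign was the same on all 3 arrays for 58.4% of the features, where independent signs would give 25%. Because the arrays share the reference RNA, their signs need not be independent, so 25% is not a bound for no change. The counts depended on the preps. Without prep 1 they were 3211 higher and 3464 lower, without prep 3 they were 174 and 212, and without prep 4 they were 631 and 617.

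The named gene with the lowest ratio was cpg-2 (B0280.5), a chondroitin proteoglycan of the eggshell, at -5.18 ± 0.32, which is 36.3-fold lower in glp-4 L3 (adjusted p = 0.0025). The related cpg-3 (R06C7.4) was at -4.77 ± 0.12. The RNA-binding zinc finger genes pos-1 (F52E1.1), which acts in embryonic cell fate, and oma-2 (ZC513.6), which acts in oocyte maturation, were at -5.17 ± 0.93 and -4.48 ± 0.71. The germline Y-box gene cey-3 (M01E11.5) was at -4.62 ± 0.88, and mesp-1 (C28C12.2), of the meiotic spindle, was at -4.44 ± 1.24. The small heat shock genes sip-1 (F43D9.4) and hsp-12.6 (F38E11.2) were at -4.84 ± 0.47 and -4.64 ± 0.77. The others of the 12 lowest were trcs-1 (F27C8.6) at -4.87 ± 0.21, the C-type lectin gene clec-87 (C25A1.8) at -4.78 ± 0.28, the glutamine synthetase gene gln-6 (C28D4.3) at -4.48 ± 0.37, and EEED8.3 at -4.43 ± 0.45. All 12 passed the threshold without any single prep.

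The highest named gene was irg-5 (F35E12.5), an infection response gene, at 5.80 ± 0.48, which is 55.9-fold higher in glp-4 L3 (limma adjusted p = 0.0025). Another infection response gene, irg-4 (F08G5.6), was at 4.69 ± 1.34. The pair pud-2.1 (F15E11.1) and pud-4 (F15E11.12), named for proteins raised in daf-2 insulin receptor mutants, were at 5.35 ± 1.15 and 5.28 ± 0.39. The genes dod-24 (C32H11.12), dod-19 (ZK6.10) and dod-21 (C32H11.10), named as downstream of the transcription factor DAF-16, were at 4.63 ± 0.81, 4.34 ± 0.73 and 4.83 ± 3.28. The dod class, tested after its values were seen, had 6 of 10 higher and 2 lower and did not pass as a group (camera adjusted p = 0.16 over 148 classes, and 0.818 with an estimated correlation). The cytochrome P450 gene cyp-35A5 (K07C6.5) was at 4.59 ± 2.82, and cld-1 (C32H11.9) at 5.39 ± 2.28. The remaining 3 were mbug-1 (F55G11.4) at 4.28 ± 0.08, C14C6.5 at 4.19 ± 0.30 and C29F3.7 at 4.18 ± 0.58. The large SDs of cld-1, dod-21 and cyp-35A5 came from prep 1, where they were at 2.92, 1.14 and 1.36, against 5.85, 5.96 and 5.83 with prep 3. Of these 12 genes, 12 passed without prep 1, 9 without prep 3 and 10 without prep 4. Related genes such as dod-21 and dod-24 can share signal through cross-hybridisation. The values of cld-1 and dod-21 were close with prep 3 and with prep 4 (7.407 and 7.405 with prep 4), and apart with prep 1. Whether these genes share signal was not tested, so they may not count as separate results.

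**Figure D1:**
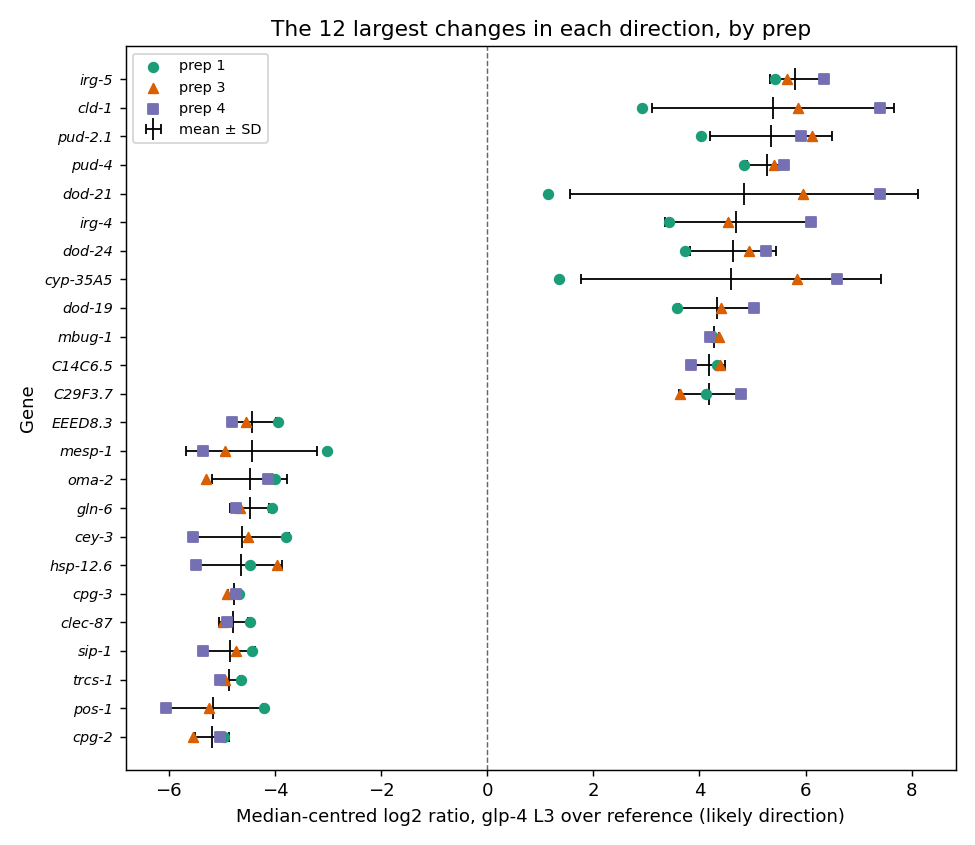
Median-centred log2 ratios, glp-4 L3 over reference in the likely direction, of the 12 named genes with the largest mean change in each direction (vertical axis). Symbols are preps 1, 3 and 4 and black bars are the mean ± SD; dod-21 runs from 1.14 with prep 1 to 7.41 with prep 4, while mbug-1 stays between 4.21 and 4.37.

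Genes of the germ line lay below the reference in each of 4 lists. The direction of the ratio was read partly from genes of this kind, so the side on which they lie is not independent evidence. In the oocyte and maternal list, 31 of 37 measured genes were lower and none was higher, with a list median of -2.78; cpg-2, pos-1, cey-3 and oma-2 led it. In the meiosis list, 24 of 30 were lower and none higher, with a median of -1.63. Its lowest members were him-3 (-2.99 ± 0.19) and htp-1 (-2.86 ± 0.57), of the chromosome axis, zim-2 (-2.78 ± 0.78), of homolog pairing, and syp-2 (-2.47 ± 0.04), of the synaptonemal complex. In the sperm list, 39 of 58 were lower and none higher, with a median of -2.12, led by the major sperm protein genes msp-78 (-3.94 ± 0.53), msp-77 (-3.94 ± 0.72), msp-56 (-3.89 ± 0.38) and msp-57 (-3.83 ± 1.29). These sperm genes are near-identical copies, so their probes cannot be read as independent. The sperm result rested mainly on them. In gene classes grouped after the data were seen, msp had 28 of 30 lower (median -3.18) and ssp 5 of 11. The spe class, of which the list holds some members, had 0 of 24 lower and 0 higher (median -0.09). In the list of germline regulators and P granules, 17 of 32 were lower and none higher, with a median of -1.15. Its lowest members were the Argonaute gene wago-1 (-3.15 ± 0.88), the P granule gene pgl-1 (-2.61 ± 0.23), the translational repressor gene gld-1 (-2.36 ± 0.66) and the RNA helicase gene cgh-1 (-2.29 ± 0.48). Adjusted over the list alone, the lower counts were 32, 26, 43 and 24 in the order given here, and with all 3 preps no member was higher at an unadjusted limma p under 0.05; without prep 1, 1 meiosis gene was higher past the adjusted threshold.

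All 4 lists were below the other genes by camera, with adjusted p = 1.46e-18 for oocyte and maternal, 2.01e-14 for meiosis, 1.65e-16 for sperm and 4.09e-10 for germline regulators. With an estimated correlation, a test with 2 residual degrees of freedom, the calls were lost, at adjusted p = 0.151, 0.151, 0.297 and 0.161. The estimate for meiosis was 0.004, below the preset 0.01, so a larger correlation was not why that call was lost. Against no change, by fry, the 4 lists were lower at adjusted p = 0.0105, 0.0105, 0.0248 and 0.0116. Without prep 3 the lower counts of the oocyte, meiosis, sperm and germline regulator lists were 19, 6, 16 and 2. Without prep 4 the oocyte, sperm and germline regulator lists held 24, 31 and 12 lower genes.

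Genes of DNA replication and mitosis were also below the reference: 33 of 48 were lower and none higher (none at an unadjusted p under 0.05), with a median of -1.13. The cyclin B genes cyb-3 and cyb-1 were at -2.95 ± 0.19 and -2.77 ± 0.37, the replicative helicase gene mcm-7 at -2.28 ± 0.06 and the DNA clamp gene pcn-1 at -2.06 ± 0.28. The list was below the other genes by camera (adjusted p = 1.69e-16), which was lost with an estimated correlation (adjusted p = 0.297), and 40 genes were lower adjusted over the list alone. Without prep 3 the lower count was 8, and without prep 4 it was 18; without prep 1, 1 gene was higher. Of histone genes, 4 of 55 were higher and 2 lower, with a median of 0.12 (0.37, 0.14 and -0.11 with preps 1, 3 and 4; camera adjusted p = 0.14, and above the other genes without prep 4 at 0.00969), and 3 higher and 2 lower adjusted over the list alone. The higher ones were his-7 (1.30 ± 0.25), his-3 (1.10 ± 0.62), his-4 (1.02 ± 0.19) and his-44 (0.91 ± 0.32), and the lower ones were his-74 (-1.86 ± 0.57) and the linker histone gene his-24 (-0.92 ± 0.15). Histone copies are close in sequence. The higher and lower histone counts were 7 and 6 without prep 1, 0 and 0 without prep 3, and 1 and 1 without prep 4.

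The yolk protein genes were also low. Of 3 measured vitellogenin genes, vit-5 (-3.91 ± 1.39) and vit-2 (-3.14 ± 1.62) were lower, and vit-6, added after its value was seen, was at -3.02 ± 2.16 without passing the threshold (limma adjusted p = 0.056). Adjusted over the list alone, 3 were lower. The list median was -1.28 with prep 1, -4.30 with prep 3 and -4.24 with prep 4. Camera placed the list below the other genes (adjusted p = 0.0098), which was lost with an estimated correlation (adjusted p = 0.373). Against no change, by fry, the list did not pass (adjusted p = 0.0889). Without prep 1 there were 3 lower genes, without prep 3 there was none and without prep 4 there was 1. Zygotic and maternal regulators of embryonic patterning were mostly near 0: 3 of 30 were lower and none higher, with a median of -0.14 (camera adjusted p = 0.191; against no change, fry gave lower at adjusted p = 0.0167), and 2 lower adjusted over the list alone. The 3 were the Wnt gene mom-2 (-1.85 ± 0.32), the caudal homeobox gene pal-1 (-1.79 ± 0.26) and sdz-28 (-0.90 ± 0.42). At an unadjusted limma p under 0.05, 6 were lower and 0 higher. There were 7 lower genes and 1 higher without prep 1, none past the threshold without prep 3, and 2 lower without prep 4.

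**Figure D2:**
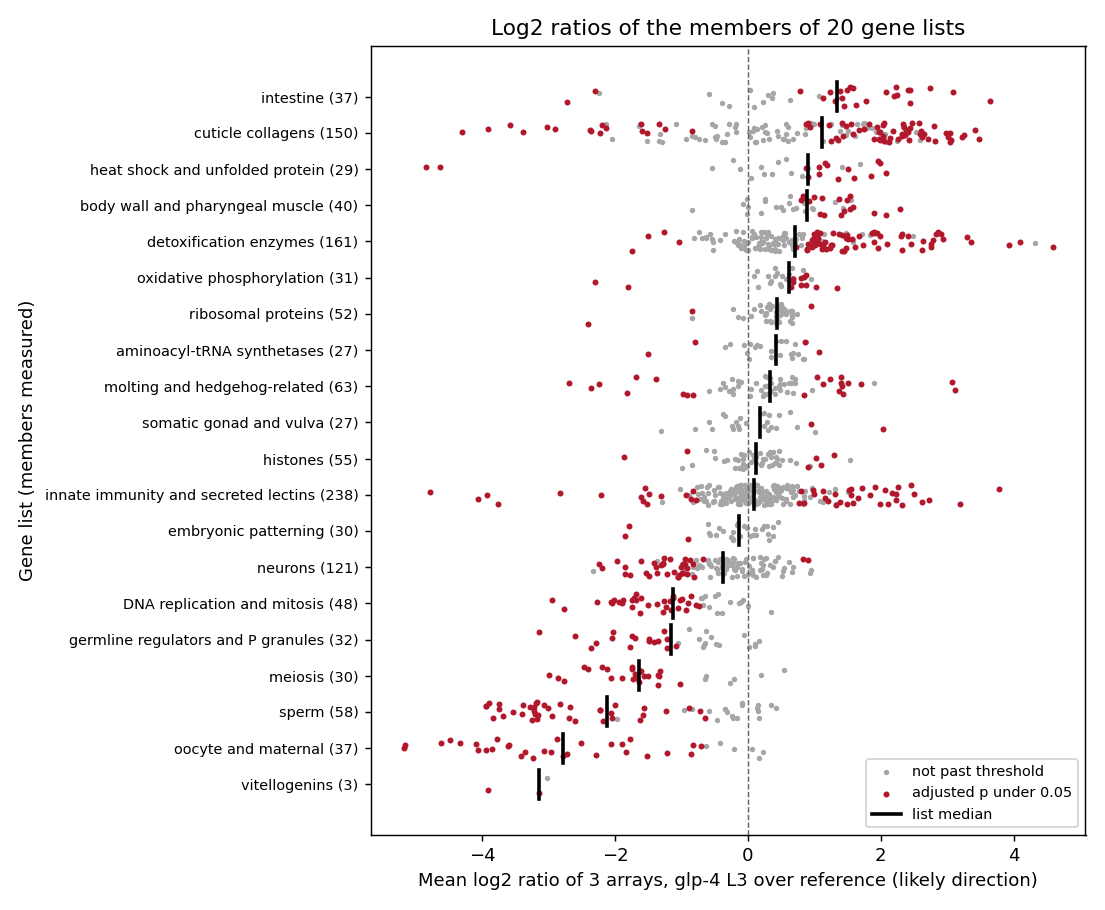
Mean log2 ratio of the 3 arrays, glp-4 L3 over reference in the likely direction, for each measured member (points) of the 20 gene lists (vertical axis, members measured in brackets); red points passed an adjusted p of 0.05 and black lines are list medians. Medians run from -3.14 for the vitellogenins to 1.34 for the intestine list.

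Intestinal genes were above the reference, with 22 of 37 higher and 2 lower and a median of 1.34. The cathepsin B-like protease gene cpr-5 was at 3.64 ± 0.66, the P-glycoprotein transporter gene pgp-1 at 3.09 ± 0.97, the peptide transporter gene pept-1 at 2.74 ± 0.38 and the sodium-proton exchanger gene nhx-2 at 2.44 ± 0.19. The small heat shock gene hsp-12.3 (-2.72 ± 1.04) and the ferritin gene ftn-1 (-2.3 ± 0.36) were lower. Camera placed the list above the other genes (adjusted p = 5.63e-09), which was lost with an estimated correlation (adjusted p = 0.151); 25 were higher and 3 lower adjusted over the list alone, and without prep 3 the higher count was 9. The lower count was 4 without prep 1 and 1 without prep 3.

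Muscle genes were higher too, 18 of 40 with none lower (0 at an unadjusted limma p under 0.05) and a median of 0.90. They included the troponin genes unc-27 (2.29 ± 0.39) and tnt-2 (1.89 ± 0.05), dim-1 (2.08 ± 0.57) and the myosin heavy chain gene myo-3 (1.58 ± 0.35). The list median was 0.23 with prep 1, 1.08 with prep 3 and 1.17 with prep 4. The list was above the other genes by camera (adjusted p = 2.09e-09), and with an estimated correlation the call was lost (adjusted p = 0.342); 23 were higher adjusted over the list alone. The higher count was 31 without prep 1, with 1 gene lower, 2 without prep 3 and 4 without prep 4. In the somatic gonad and vulva list, 2 of 27 were higher and none lower, with a median of 0.18 (camera adjusted p = 0.427; against no change, fry gave higher at adjusted p = 0.0396), and 1 higher adjusted over the list alone. Both encode basement membrane proteins: nidogen, nid-1 (2.03 ± 0.36), and laminin beta, lam-1 (0.95 ± 0.48). At an unadjusted limma p under 0.05, 6 were higher and 2 lower. The higher and lower counts were 3 and 2 without prep 1, 0 and 0 without prep 3, and 1 and 0 without prep 4.

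The neuron list lay on the other side of the reference from muscle and intestine, with 34 of 121 lower and 2 higher and a median of -0.38. Its flp and nlp genes, a neuropeptide group, were taken by name alone, and whether each is expressed in neurons was not checked. Of these, 30 of 75 were lower and 2 higher, with a median of -0.69. Of the other 46 list members, 4 were lower and none higher, with a median of -0.07. The lower members of the list included nlp-12 (-2.24 ± 0.33), nlp-32 (-1.97 ± 0.18) and flp-15 (-1.85 ± 0.13), and tdc-1 (-2.19 ± 0.51), the tyrosine decarboxylase gene of tyramine synthesis. The genes nlp-22 (0.90 ± 0.43) and nlp-36 (0.83 ± 0.32) were higher. The whole list was below the other genes by camera (adjusted p = 5.11e-06), a call lost with an estimated correlation (adjusted p = 0.327), and 39 were lower and 4 higher adjusted over the list alone. The lower and higher counts were 48 and 8 without prep 1, 4 and 0 without prep 3, and 10 and 0 without prep 4.

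Cuticle collagen genes were split, with 58 of 150 higher, 17 lower and a median of 1.11. The highest were col-150 (3.48 ± 0.46), col-161 (3.42 ± 0.40), col-126 (3.25 ± 0.67) and col-180 (3.23 ± 1.67), and the lowest were col-36 (-4.30 ± 0.99) and col-84 (-3.91 ± 0.44). Camera placed the list above the other genes (adjusted p = 1.99e-07), which was lost with an estimated correlation (adjusted p = 0.297). Adjusted over the list alone, 77 were higher and 21 lower. The higher and lower counts were 74 and 32 without prep 1 and 24 and 8 without prep 3. The molting and hedgehog-related list was also mixed, with 13 of 63 higher and 9 lower and a median of 0.34. Its highest members were the hedgehog-related grd-14 (3.11 ± 0.60) and grd-5 (1.51 ± 0.10), phat-4 (3.07 ± 0.44) and the astacin protease gene nas-36 (1.70 ± 0.40), and its lowest were the ground-like genes grl-20 (-2.70 ± 0.25) and grl-3 (-2.36 ± 0.30). Camera gave adjusted p = 0.0198, lost with an estimated correlation (adjusted p = 0.331) and without prep 1 (adjusted p = 0.104), and fry, against no change, gave adjusted p = 0.0889; adjusted over the list alone, 19 were higher and 10 lower. The higher and lower counts were 20 and 12 without prep 1, 2 and 3 without prep 3, and 7 and 4 without prep 4.

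Detoxification enzymes, the cytochromes P450, glucuronosyltransferases and glutathione transferases, were higher for 63 of 161 genes and lower for 4, with a median of 0.72. By class, grouped after the data were seen, ugt had 34 of 62 higher and 0 lower, and cyp had 21 of 66 higher and 1 lower. The gst class had 8 of 30 higher and 3 lower and did not pass (camera adjusted p = 0.119 over 148 classes). Beside cyp-35A5, the highest were ugt-8 (4.09 ± 2.07), ugt-63 (3.93 ± 0.75) and ugt-22 (3.35 ± 1.33), and the lowest were gst-9 (-1.75 ± 0.54) and gst-41 (-1.50 ± 0.17). The list was above the other genes by camera (adjusted p = 6.76e-12), a call lost with an estimated correlation (adjusted p = 0.297), and 77 were higher and 7 lower adjusted over the list alone. The higher and lower counts were 84 and 11 without prep 1, 9 and 0 without prep 3, and 30 and 2 without prep 4. The list of innate immunity genes and secreted lectins had 34 of 238 higher and 16 lower, with a median of 0.10 (camera adjusted p = 0.0818, and 0.0241 without prep 3; against no change, fry gave higher at adjusted p = 0.0463), and 36 and 16 adjusted over the list alone. The lectin genes clec-52 (3.78 ± 0.28), clec-57 (3.19 ± 0.48), clec-56 (2.73 ± 0.54) and clec-49 (2.63 ± 0.25) were highest, and clec-87 and clec-91 (-4.06 ± 0.38) were lowest. The higher and lower counts were 53 and 36 without prep 1, 11 and 6 without prep 3, and 26 and 6 without prep 4.

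In the heat shock and unfolded protein list, 13 of 29 were higher and 2 lower, with a median of 0.90. The higher members included the small heat shock genes hsp-16.1 (2.08 ± 0.85) and hsp-16.11 (1.98 ± 0.80), which are near-identical copies, the endoplasmic reticulum chaperone gene hsp-3 (1.96 ± 0.17) and the DnaJ gene dnj-7 (1.85 ± 0.63), whereas sip-1 and hsp-12.6 were the lower ones. Camera gave adjusted p = 5.65e-05, lost with an estimated correlation (adjusted p = 0.394), and fry, against no change, gave adjusted p = 0.0944; 18 were higher and 2 lower adjusted over the list alone. The list median was 0.34 with prep 1, 1.16 with prep 3 and 1.03 with prep 4. The higher count was 1 without prep 3 and 3 without prep 4, and the lower count was 3 without prep 1.

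Of genes of oxidative phosphorylation, 10 of 31 were higher and 2 lower, with a median of 0.62 (camera adjusted p = 4.07e-06). The call was lost with an estimated correlation (adjusted p = 0.275), and 21 were higher and 2 lower adjusted over the list alone. The complex I genes gas-1 (1.33 ± 0.41), nuo-1 (1.02 ± 0.25) and nuo-4 (0.87 ± 0.13) and the ATP synthase subunit gene asb-2 (0.88 ± 0.31) were higher. The other copy of that subunit, asb-1 (-1.80 ± 0.10), and the complex III gene ucr-2.3 (-2.3 ± 0.58) were lower. Ribosomal protein genes had a median of 0.44 (0.17, 0.65 and 0.47 with preps 1, 3 and 4), with 1 of 52 higher and 2 lower past the threshold. A pair of copies of the same ribosomal protein were apart, rpl-11.1 at -2.41 ± 0.10 and rpl-11.2 at 0.94 ± 0.30. The third gene past the threshold was rpl-42 (-0.84 ± 0.04), where each probe tested alone did not agree: the weaker was at -0.25 (limma adjusted p = 0.415). Camera gave adjusted p = 1.9e-05 for the ribosomal list, lost with an estimated correlation (adjusted p = 0.462); fry, against no change, gave adjusted p = 0.11, and none was higher and 1 lower adjusted over the list alone. Aminoacyl-tRNA synthetase genes had a median of 0.43 (-0.07, 0.76 and 0.54 with preps 1, 3 and 4), with 2 of 27 higher, dars-1 (1.06 ± 0.51) and gars-1 (0.86 ± 0.29), and 2 lower, fars-1 (-1.50 ± 0.94) and rars-2 (-0.80 ± 0.18). Camera gave adjusted p = 0.0198, lost with an estimated correlation (adjusted p = 0.645), without prep 3 (adjusted p = 0.166) and without prep 4 (adjusted p = 0.0715), and fry, against no change, gave adjusted p = 0.363; 2 were higher and 1 lower adjusted over the list alone. Without prep 1 the higher counts of the oxidative phosphorylation, ribosomal and synthetase lists were 16, 18 and 12, and without prep 3 or prep 4 each was 0. Their lower counts, in that order, were 2, 3 and 2 without prep 1, 0, 1 and 0 without prep 3, and 2, 1 and 0 without prep 4.

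The preps differed in how closely they matched. Across the 19580 features, which are not independent replicates, preps 3 and 4 had Pearson's r = 0.836 and Spearman's rho = 0.819. Prep 1 had r = 0.657 and rho = 0.562 with prep 3, and r = 0.606 and rho = 0.55 with prep 4. No pair of arrays held identical values. The median SD between preps was 0.314 per feature.

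**Figure D3:**
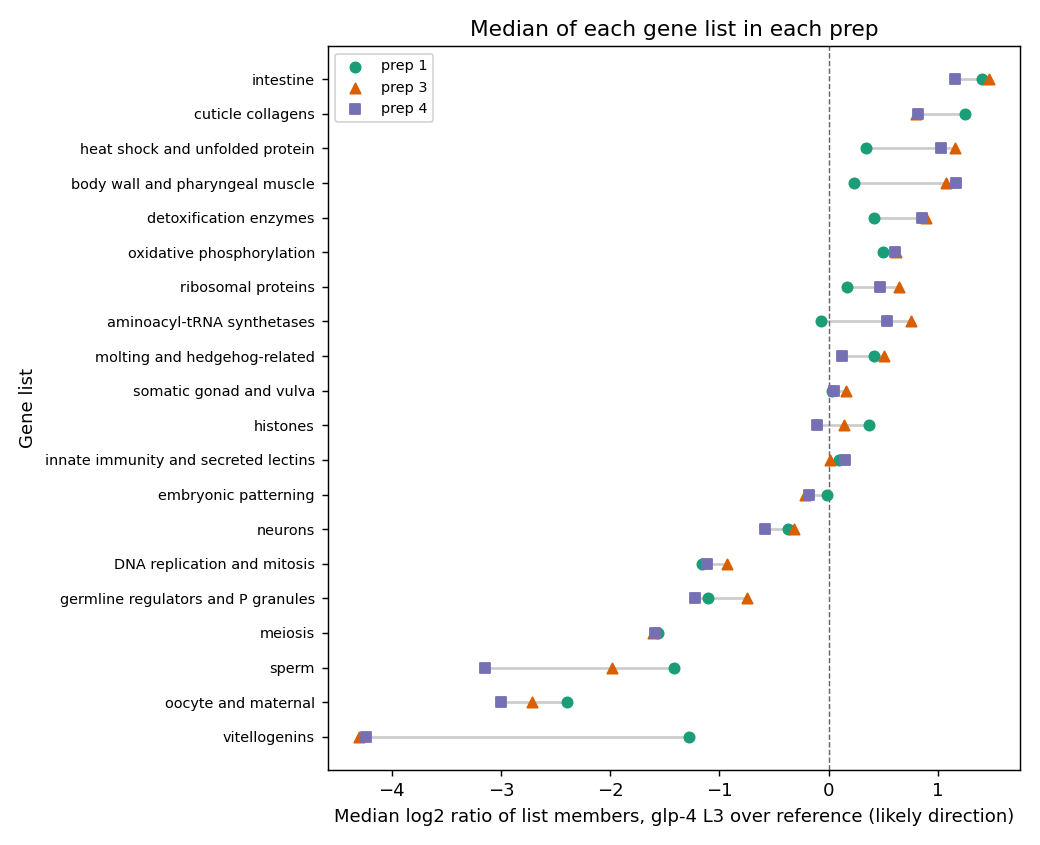
Median log2 ratio of the members of each gene list (vertical axis), glp-4 L3 over reference in the likely direction, with symbols for preps 1, 3 and 4. The meiosis list was at -1.56, -1.61 and -1.59 in the 3 preps, while the muscle list was at 0.23, 1.08 and 1.17.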

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

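The direction of each of the 108 genes named by the rule held under each alternative run, and calls moved mainly with the number and choice of preps. With array weights, chosen after seeing the data, 3938 features were higher and 4161 lower, with prep 3 weighted highest (2.682, against 0.452 for prep 1 and 0.825 for prep 4). Leaving out 1 prep gave 174 to 3211 higher and 212 to 3464 lower features, with prep 3 left out at the low end and prep 1 at the high end. At least 2-fold on every array, with no test, left 692 higher and 730 lower. Values as deposited, scaled or quantile-normalized arrays, features on 2 arrays, single probes, the robust prior and the 2-fold limit kept both counts within 1.5 times. Not centring moved the median of all features by -0.019.

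The mean correlation between preps was 0.836 without prep 1, with a range over the left-out preps of 0.606 to 0.836. With an estimated correlation in camera 0 lists passed and 4 had an unadjusted p under 0.05; the adjusted p was 0.151 for intestine, meiosis and oocyte, 0.161 for germline regulators, 0.275 for oxidative phosphorylation, 0.297 for collagens, detoxification, replication and sperm, 0.327 for neurons, 0.331 for molting, 0.342 for muscle, 0.373 for vitellogenins, 0.394 for heat shock, 0.462 for ribosomal proteins and 0.645 for tRNA synthetases. This test has only 2 residual degrees of freedom. Among the lists past camera, the estimated correlation ran from 0.004 for meiosis and intestine to 0.995 for vitellogenins. For meiosis and intestine it was below the preset 0.01, so a larger correlation was not why their calls were lost. Fry tests a list against no change, not against other genes; of the lists past camera, tRNA synthetases (0.363), heat shock (0.0944), molting (0.0889), ribosomal proteins (0.11) and vitellogenins (0.0889) did not pass it, and of the others embryonic patterning (lower, 0.0167), immunity (higher, 0.0463) and somatic gonad (higher, 0.0396) did. Over the left-out preps, the adjusted p ran from 0.000406 to 0.166 for tRNA synthetases, 0.00969 (higher, without prep 4) to 0.774 for histones, 0.0241 (higher, without prep 3) to 0.26 for immunity and 0.000779 to 0.104 for molting. Camera on ranks and the other scalings, filters and array weights changed no list call. With an estimated correlation, the correlation and the degrees of freedom changed together. Their parts were not told apart for the lists past camera other than meiosis and intestine. Why calls moved with fry or between left-out preps was not tested. Of the 108 genes, 58 passed without prep 3, 83 without prep 4 and 107 without prep 1; in the other settings between 101 and 108 kept their call. No paired analysis was possible because the design holds a single group. The random block by array series could not be fitted.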

Other observations

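Tests in this part chosen after the data were seen are those of the gene classes, of array series, of the molting genes' difference between preps 3 and 4, of the spread of other lists and of the sign patterns. Genes were also grouped by the class in their names, and members named in this part without a place in the fixed rule were chosen after their values were seen. Of 148 gene classes with at least 10 measured members, 25 were above and 9 below the other genes by camera (limma, adjusted over the classes), and with an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05. The estimated-correlation test has only 2 residual degrees of freedom. Even msp, with 28 of 30 genes lower, did not pass it (adjusted p = 0.818), so failing it says little about a class. These 148 include classes that the fixed lists hold, such as msp, col and ugt. The abu class, named for genes activated when the unfolded protein response is blocked, had 11 of 13 genes higher and none lower, with a median of 2.06 (adjusted p = 1.32e-08, and 0.818 with an estimated correlation); abu-15 was at 2.88 ± 0.54. Genes of the vacuolar proton pump, class vha, had 13 of 17 higher, with a median of 1.04 (adjusted p = 1.12e-05, and 0.818 with an estimated correlation); vha-6, which the intestine list also holds, was at 2.2 ± 0.18, and the single lower member, vha-18, was at -2.97 ± 0.22. P-glycoprotein genes, class pgp, had 8 of 14 higher and none lower, with a median of 1.24 (adjusted p = 9.34e-06, and 0.818 with an estimated correlation); pgp-6 was at 3.35 ± 1.00, and the intestine list holds pgp-1, pgp-2 and pgp-3 of this class.

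On the lower side, 7 of 16 genes of the SKP1-related class skr were lower and 1 higher, with a median of -0.55 (limma camera adjusted p = 0.00153, and 0.818 with an estimated correlation). In this class skr-8 was at -2.32 ± 0.46, skr-2 at -1.95 ± 0.19 and skr-3 at 1.60 ± 0.42. The related classes of MATH-domain genes lay apart: math had 11 of 42 higher and 1 lower, with a median of 0.58 (adjusted p = 0.000138), and bath had 11 of 29 lower and none higher, with a median of -0.54 (adjusted p = 0.00315); both had an adjusted p of 0.818 with an estimated correlation. Members of these classes are related in sequence, so probes can share signal.

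The spread of the log ratios differed between preps, narrowest with prep 1. If genes are taken as independent, a single compression factor on the prep 1 array is argued against. The median of prep 1 over that of preps 3 and 4 was 0.96 (95% bootstrap interval 0.73 to 1.11) for meiosis and 0.21 (0.12 to 0.56) for muscle. Intervals did not overlap for 38 of 78 pairs of lists, with no adjustment over pairs. The bootstrap resampled genes, which are not independent replicates (estimated correlation 0.369 for muscle), so its intervals may be too narrow. The vitellogenin list, with only 3 measured genes, was left out of these pairs. Collection of the preps at different points of the molting cycle stays open. The median SD between preps of 213 collagen and molting genes, arrays scaled to the same spread, was 0.679 against 0.493 for matched random lists (percentile 100 of 10000). Between preps 3 and 4 alone, unscaled, their median difference was 0.473 against 0.343. By the scaled SD, the 150 collagens were at 0.772 against 0.562 (percentile 100), and the 63 molting and hedgehog-related genes at 0.477 against 0.381 (percentile 97.3). A spread above matched lists was not particular to them, since histones (0.448 against 0.303) were also at percentile 100, DNA replication and mitosis at 97.6 and tRNA synthetases at 97.2, so it does not single out the molting cycle. Array series stays open too, because prep 1 is alone in its series, and the date in the array titles cannot be told apart from it. Over the 19580 tested features, not all probes, the SD differed by 0.178 between preps 3 and 4 and by 0.242 between preps 1 and 3.

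The neuron list lay below the reference, which holds an unstated mix of stages. A lower share of neural tissue in the L3 preps could lower neuronal genes alike. That holds only for genes equally restricted to neurons and equally far above background, neither of which was known here. The 19 pan-neuronal and synaptic members had a median of -0.15, with 3 lower, and the 75 flp and nlp neuropeptide genes had a median of -0.69, with 30 lower and 2 higher. The medians differed by 0.54 (two-sided permutation test over genes, which are not independent replicates, p = 0.018), so the groups were not lowered alike. This cannot decide on dilution, because the groups may differ in background or in expression outside neurons. A difference of genotype or stage in the flp and nlp genes, which were taken by name alone, stays open and was not tested.

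The ratios of genes next to each other in the reference gene order were weakly correlated. Over 11236 neighbouring pairs, Spearman's rho was 0.162, where 2.5% of shuffled pairings lay above 0.019. Cross-hybridisation between neighbouring copies of a family was tested by keeping the 3903 pairs with different name stems, where rho was 0.135 (shuffled limit 0.031), so copies that share a name are not the whole cause. Copies under different names, operons and shared regulatory regions may each contribute and were not told apart. The shuffling crossed chromosomes, so a difference between whole chromosomes could also lift rho above the shuffled limit.

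The number of features past the threshold was compared with other sign patterns of the arrays (limma). The real pattern gave 3255 features, and the highest of the 3 others gave 0, with up to 455 at an unadjusted p under 0.05 against 6914 in the real pattern. With 1 of 4 patterns the share cannot fall under 0.05. The arrays agreed (Pearson's r from 0.606 to 0.836), so turning 1 of them would lower the count whatever made them agree. The comparison therefore cannot tell a change in glp-4 L3 from an effect shared by the arrays.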
